A study of Homo sapiens with 6 samples.

How the data were processed

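RNA from 6 samples of ARPE-19 cells, 3 in each of 2 groups, was amplified and biotin-labelled with a 3′ IVT kit and hybridised to 1 Affymetrix array per sample, per the labels' protocols. The deposited table holds a log2 value for each of 49372 probe sets. That scale was read from the values, which have a median of 5.30 to 5.34 on every array and run from 1.54 to 14.3. The submitters' processing notes name MAS5 and RMA, without a version, role or order. The nearly equal distributions and the log2 scale are those that RMA gives, and the software, annotation and filters behind the deposited values are not given in the sources used here. RMA forces one distribution on all arrays, so a change of the total amount of RNA cannot be seen in such values.

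Groups were taken from the sample titles. The descriptions of the 3 h arrays name a different transfected construct from the protocol and the series design text, and this conflict was not resolved. Probe sets were named from the platform annotation: 44988 of those that are not controls have 1 gene symbol, 1832 have several and 2473 have none, and only those with 1 symbol were named. Identifiers of 44961 probe sets matched the gene table of assembly GRCh38.p14, and 0 symbols changed. The 79 control probe sets were left out of the tests.

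Before the data were examined, the test, the alternatives, 30 gene lists and the rule for named genes were fixed. Each gene was represented by its probe set with the highest mean over the 6 arrays, and genes under the 40th percentile of all probe sets that are not controls (log2 4.64) were left out, which removed 5911 of 18132. The 3 h and 0 h arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; p-values called adjusted are from this fit unless a list is named. Changes are 3 h minus 0 h on the log2 scale, and "rose" or "fell" is used of calls only. Gene lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 30 lists. Members of a list were also adjusted over the list alone. Figures were drawn with matplotlib 3.10.9.

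The genes named are the 12 largest increases and 12 largest decreases among calls whose groups do not overlap, passing over unnamed reading frames, antisense and non-coding symbols starting with LOC, LINC, MIR or FLJ, then up to 4 members of each list with the smallest p, then a fixed set of stress, centromere and retinal genes. Of that set, HSPA1A had no probe set with a single symbol, and RPE65, RLBP1 and SNAI2 were under the floor. The same step was tested on simulated data for the comparison of 3 h with 0 h over 12221 genes: 96 of 100 genes changed by 1 on the log2 scale and 79 of 100 changed by 0.5 were called, with 7 unchanged genes called. The simulation drew independent noise for each gene, with 200 genes changed and no batch. It therefore does not measure the rate of false calls in the real comparison.

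Alternatives covered quantile normalization, median centring, the filter on dim genes, the choice of probe set, the moderation of the variance, array weights, the replicate number as a block, the fold minimum, a threshold of 0.01 and leaving out each array. After the data were seen, the loess trend (span 0.5) of each array on the number of protein-coding genes within 500 kb was removed as a further alternative; the file names no genome build, and the gene table served here only for which genes lie near each other. Intervals of 95% for list medians came from 10000 bootstrap draws of the members, and those for correlations across genes from 1000 draws. Genes are not independent, so these intervals are too narrow. The exact binomial intervals for shares of probe sets share that limit. The base composition and length of transcripts were not analysed here.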

Results

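Gene expression was measured in ARPE-19, an established cell line derived from human retinal pigment epithelium, with and without exposure to glucose oxidase. This enzyme makes hydrogen peroxide as it oxidises the glucose of the medium. By their protocol, all cells were transfected with a plasmid for green fluorescent protein and 48 h later either received 10 mU/ml glucose oxidase for 3 h (3 arrays) or did not (0 h, 3 arrays). The sample titles give the exposure and name no plasmid. The sample descriptions give another transfection for the 3 h arrays, a fluorescent protein construct with alpha satellite (a centromeric repeat), so the groups may differ in the transfected construct as well as in the treatment. The labels do not say that the replicates came from separate cultures, so the p-values may measure only technical spread. The labels also list no group kept for 3 h without the enzyme, so handling and time after transfection may differ between the groups too. Of 18132 genes with a probe set, 12221 were bright enough to test. The number of arrays limits the precision. The median SD of a gene was 0.06 among the 0 h arrays and 0.09 among the 3 h arrays on the log2 scale.

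The comparison asks which transcripts changed after 3 h of exposure to the peroxide-generating enzyme. Among the genes named, the largest increase was that of NFIC, a transcription factor of the nuclear factor I family, which went from 5.92 ± 0.03 to 7.92 ± 0.04 (log2 value, mean ± SD, n = 3). It was 4.02-fold higher with an adjusted p of 1.25e-06. GNA11, a G protein alpha subunit, rose 3.24-fold, and ZMIZ1, a transcriptional coactivator, rose 3.17-fold. CMIP, MLXIP (a glucose-sensing transcription factor), the Polycomb protein gene CBX6, GAS7, IRF2BPL, the TGF-beta repressor SKI, TRIM56, TRIM58 and the tumour suppressor NF2 completed the 12 largest increases named. Their log2 changes ran from 1.48 for NF2 to 1.68 for CMIP. The largest decrease was that of AKAP9, a scaffold protein of the Golgi and centrosome, from 7.41 ± 0.08 to 5.65 ± 0.18 (n = 3). It was 3.40-fold lower with an adjusted p of 1.08e-05. CASP1, the inflammasome protease, was 2.66-fold lower and GOLGB1, the Golgi protein giantin, 2.35-fold lower. TAF1A and BDP1, initiation factors of RNA polymerases I and III, fell by 1.22 and 1.17 on the log2 scale. SMCHD1, CFAP20DC, SNORA33, NXT2, FAM200C, PCP4 and GIN1 had log2 changes of -1.22 to -1.09, with an SD of 0.65 for SMCHD1 among the 3 h arrays. The 3 h means of CFAP20DC (4.14), FAM200C (4.15) and PCP4 (4.14) were under the floor of 4.64, which was applied to the mean over all arrays. The sizes of their decreases therefore rest on dim signal at 3 h. All sizes given so far are those of each gene's brightest probe set. Averaged over all probe sets of the gene, log2 changes shrank from 2.01 to 1.03 for NFIC, and were 1.00 for CMIP, 0.96 for MLXIP, 0.95 for NF2, 0.94 for CBX6, 0.41 for GAS7, -0.71 for SMCHD1, -0.67 for NXT2 and -0.53 for CASP1.

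In all, 2514 genes were higher and 3759 lower at 3 h at an adjusted p under 0.05 (limma), which is 51.3% of those tested. Most of these changes were small: 82.4% were under 1.5-fold, and 122 genes changed at least 2-fold, 91 of them upward. Of all calls 40.1% were upward and 59.9% downward. Counts of members called within a list are to be read against these shares, since calls in both directions are found over all tested genes. The values of the groups did not overlap for 7395 genes, 60.5% of those tested against 10% by chance. Correlations between arrays across genes were 0.997 to 0.998 within the 0 h group, 0.996 to 0.997 within the 3 h group and 0.979 to 0.983 between the groups. Control probe sets also differed between the groups: all 24 for the poly-A spike transcripts were lower on every 3 h array (median log2 change -0.60), as were 17 of 18 for the hybridization spikes. The log2 difference between the 5′ and 3′ probe sets of actin went from -2.06 ± 0.07 to -1.20 ± 0.06 (n = 3, two-sided exact permutation p = 0.1). That p is the smallest that 3 against 3 arrays allow. These control differences run along with every gene and gene group below, so a batch of RNA or array preparation and the treatment cannot be told apart. Of 143 called genes named by rule that could be averaged over all their probe sets, 41 shrank by more than 1.5 times or changed sign and 5 grew by more than that. Probe sets under the floor enter these averages, and their share in the shrinkage was not tested. Without probe sets that the platform marks as shared or cross-hybridizing, GAS7 stood at 0.00 and SMCHD1 at -0.45 on the log2 scale.

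**Figure D1:**
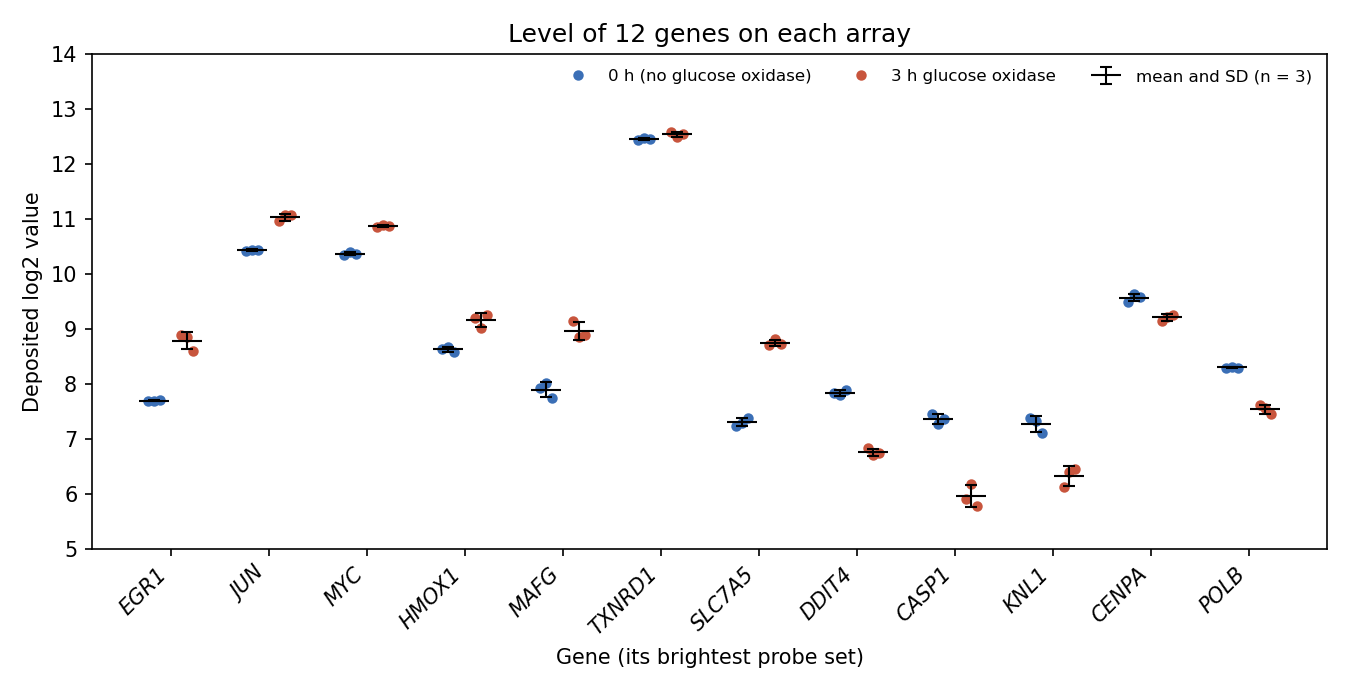
Deposited log2 value (vertical axis) of 12 genes on each of the 3 arrays at 0 h (blue) and the 3 arrays at 3 h (red), with the mean and SD of each group (n = 3) in black. EGR1 sits at 7.70 ± 0.02 at 0 h and 8.79 ± 0.16 at 3 h, whereas the group means of TXNRD1 differ by 0.08 for the probe set drawn.

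Immediate early genes, the first transcripts that cells make after a stimulus, were higher at 3 h. Of 33 tested members 14 rose, 2 fell and 17 did not pass the threshold, with the same counts adjusted over the list alone. EGR1 rose by 1.09 (SE 0.08, n = 3, adjusted p = 3.78e-05), and the transcription factor genes JUN, KLF6, MYC and ATF3 rose by 0.60, 0.57, 0.50 and 0.40. FOS differed by 0.09 with an adjusted p of 0.215. The phosphatase genes DUSP6 and DUSP1, which restrain MAP kinases, fell by 0.37 and 0.23. DUSP6 was named after its value was seen. The list stood above the other genes in camera (median log2 change 0.15, adjusted p = 0.0182 over 30 lists), with an adjusted p = 0.491 when the correlation between its genes was estimated. The call of DUSP1 ended without replicate 1 or 3 at 0 h (-0.24, -0.20) or replicate 3 at 3 h (-0.17), and averaged over its probe sets it turned to 0.11.

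Genes of the centromere and kinetochore, the structures that attach chromosomes to the spindle, were lower at 3 h. Of 28 tested members 18 fell, 1 rose and 9 did not pass, and 19 fell and 1 rose adjusted over the list alone. The outer kinetochore scaffold gene KNL1 fell by 0.95 (SE 0.10, n = 3, adjusted p = 0.000174), CENPK by 0.68, NSL1 by 0.59, MIS12 by 0.52 and CENPA, the centromeric histone H3, by 0.36. The satellite-binding protein gene CENPB stood at 0.14 (adjusted p = 0.271), or 0.21 and past the threshold averaged over its probe sets. The CENPA chaperone gene HJURP stood at -0.00 (adjusted p = 0.955), or 0.02 with median centring. CENPO, named after its value was seen, rose by 0.17. The list had a median log2 change of -0.34 and an adjusted p of 0.00242 in camera, with an adjusted p = 0.491 when the correlation was estimated. Without shared or cross-hybridizing probe sets, MIS12 no longer passed (-0.18). With estimated correlations 0 of the 30 lists passed camera and 2 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move one way and does not compare them with other genes, called 24.

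Other lists of the cell cycle and genome maintenance did not pass camera after adjustment in the main fit. Among 24 mitosis genes 12 fell and 1 rose, with the same counts adjusted over the list alone (median -0.17, adjusted p = 0.0936). CENPE, a kinetochore motor, fell by 0.86, ASPM by 0.75 and CENPF by 0.66, while PLK1, named after its value was seen, rose by 0.34. Among 29 DNA repair genes 16 fell and 2 rose, with the same counts adjusted over the list alone (median -0.25, adjusted p = 0.0508). POLB, the polymerase of base excision repair, fell by 0.76, the damage-signalling kinase gene ATM by 0.65, RAD50 by 0.54 and APTX by 0.45. The 3 other probe sets of ATM above the floor changed by less, -0.33 to -0.21. FEN1 and PARP1, named after their values were seen, rose by 0.19 and 0.25. DNA replication genes went the other way in more cases, with 7 of 21 higher and 3 lower, the same adjusted over the list alone (median 0.09, adjusted p = 0.238). UHRF1 rose by 0.54, CCNA2 fell by 0.32 and CCNE2 fell by 0.59, or -0.12 and not called averaged over its probe sets. RRM1, named after its value was seen, fell by 0.19. Averaged over all their probe sets, CENPF stood at -0.42 and CCNA2 at -0.15. With the trend on gene density removed, an alternative chosen after seeing the data, DNA repair genes passed camera with a median of -0.16. With the trend kept, they had an adjusted p = 0.491 with an estimated correlation.

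**Figure D2:**
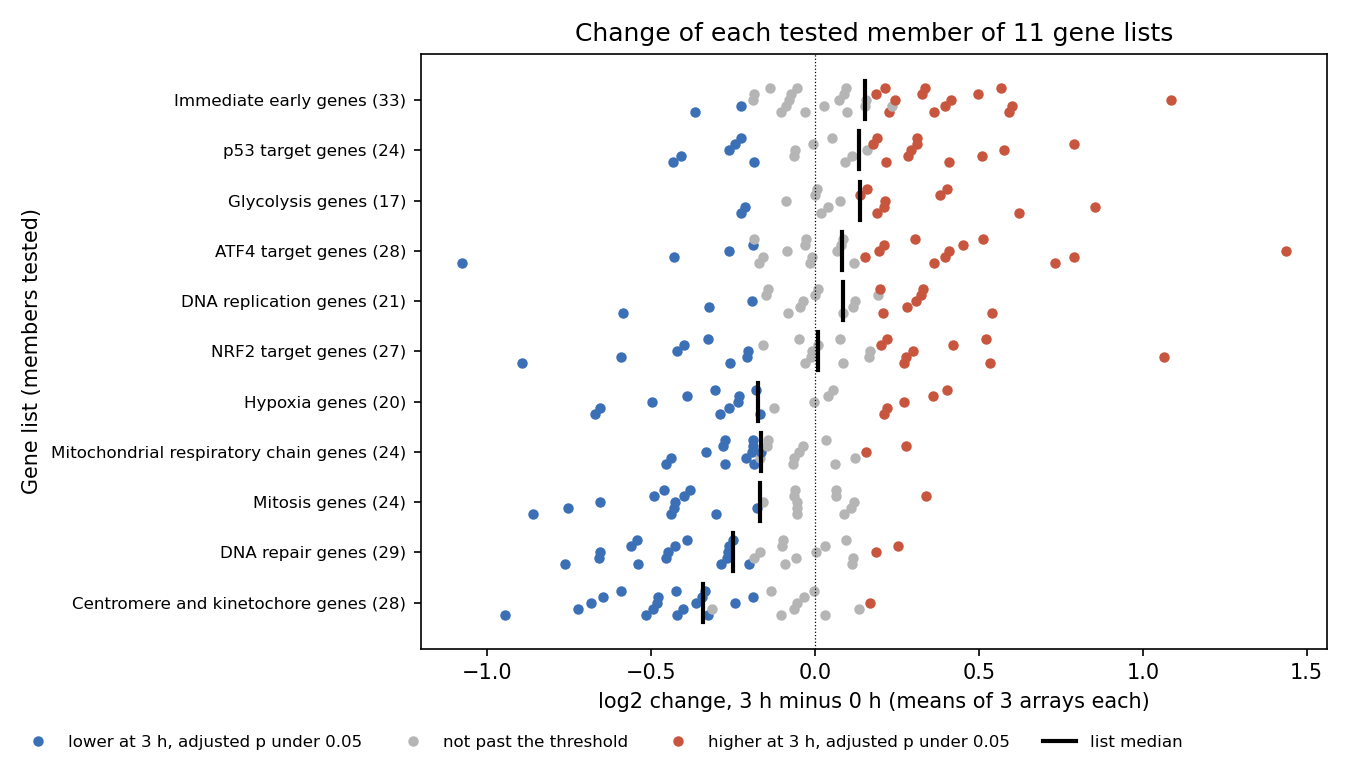
Log2 change from 0 h to 3 h (horizontal axis) of each tested member of 11 gene lists (vertical axis), coloured by whether it was higher, lower or not past an adjusted p of 0.05, with the median of each list as a black bar. Among the lists drawn, the medians run from -0.34 for centromere and kinetochore genes to 0.15 for immediate early genes, and every list has members on both sides of 0. Retinal pigment epithelium markers and NF-kB targets, which are not drawn, had higher medians (0.18 and 0.17).

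Targets of NRF2, the regulator of the antioxidant response, were split, as were the calls over all tested genes. Of 27 tested, 9 rose, 8 fell and 10 did not pass, and 10 rose and 9 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.454). The heme oxygenase gene HMOX1 rose from 8.63 ± 0.05 to 9.16 ± 0.12 (n = 3, adjusted p = 0.000487), the NRF2 partner gene MAFG rose by 1.07, OSGIN1 by 0.52 and the sulfiredoxin gene SRXN1 by 0.28. NQO1 fell by 0.21 and AKR1C3 by 0.42, and TXNRD1 stood at 0.08 (adjusted p = 0.208). Without shared or cross-hybridizing probe sets TXNRD1 was called at 0.57. Of 26 other antioxidant enzymes 4 rose and 6 fell, and 3 and 6 adjusted over the list alone (median -0.09, adjusted p = 0.674). The largest falls named were those of the selenoprotein P gene SELENOP, which fell by 1.07, and the glutaredoxin gene GLRX, which fell by 0.71. PRDX2 and SOD3 rose by 0.28 and 0.24, as did GPX3 and TXNRD2 by 0.21 and 0.16, both named after their values were seen, and SOD3 was not called without shared or cross-hybridizing probe sets (0.10). Averaged over all their probe sets, AKR1C3 stood at -0.26, NQO1 at -0.12 and GLRX at -0.45, and GLRX stood at -0.24 without shared or cross-hybridizing ones. Of 6 metallothioneins, which bind metals, 4 fell, the same adjusted over the list alone (median -0.26, adjusted p = 0.195). MT1G fell by 0.45, MT1M by 0.37, MT1F by 0.36 and MT1X by 0.17, and the call of MT1X ended when any single 0 h array was left out (-0.19 to -0.15) and without replicate 2 or 3 at 3 h (-0.16, -0.13). At an unadjusted p under 0.05, 8 of the 30 lists passed camera. TXNIP stood at -0.04 (adjusted p = 0.540) and turned to 0.22 without shared or cross-hybridizing probe sets.

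Stress pathways of proteins and amino acids were mixed as well. Of 28 targets of ATF4, a factor of the integrated stress response, 12 rose and 4 fell, and 12 and 5 adjusted over the list alone (median 0.08, adjusted p = 0.0950). The amino acid transporter gene SLC7A5 rose 2.71-fold (log2 1.44, or 0.89 averaged over its probe sets), SESN2 rose by 0.79 and ATF5 by 0.73, while the mTORC1 inhibitor gene DDIT4 fell by 1.08 and DDIT3 stood at -0.09 (adjusted p = 0.192). PSAT1, MTHFD2 and VLDLR, named after their values were seen, fell by 0.43, 0.26 and 0.19. Of 18 endoplasmic reticulum stress genes 6 rose and 5 fell, the same adjusted over the list alone: the chaperone gene CALR rose by 0.98 and DNAJB9 fell by 0.69. Named after their values were seen, CRELD2 fell by 0.30, HSPA5, the main chaperone of that compartment, by 0.20, MANF by 0.17 and DNAJB11 by 0.16. Of 19 heat shock genes 8 rose and 6 fell, the same adjusted over the list alone, with the co-chaperone gene BAG3 rising by 0.48 and HSPA4L falling by 0.53. Camera gave adjusted p values of 0.522 and 0.806 for these 2 lists and placed both upward although their medians were -0.02 and -0.08 (means 0.06 and -0.05). Of 24 p53 targets 11 rose and 6 fell, the same adjusted over the list alone (median 0.14, adjusted p = 0.180). SESN2, which is also on the ATF4 list, MDM2 (0.51), GDF15 (0.41) and the cell cycle inhibitor gene CDKN1A (0.18) rose, and CCNG1 and TIGAR fell by 0.43 and 0.41. The call of MDM2 ended without replicate 3 at 0 h (0.41), that of GDF15 without replicate 1 or 2 at 0 h (0.28, 0.44) or replicate 1 at 3 h (0.28), and that of CDKN1A when any single 0 h array was left out (0.17 to 0.18). Without shared or cross-hybridizing probe sets CDKN1A stood at 0.02 and CCNG1 at -0.07, the p53 target TNFRSF10B turned from 0.58 to -0.05 and the endoplasmic reticulum gene PDIA3 turned from 0.47 to -0.10. Averaged over all their probe sets, CALR stood at 0.64, DNAJB9 at -0.42, MDM2 at 0.31 and TIGAR at -0.23.

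Inflammatory genes moved in both directions. Of 21 NF-kB targets 9 rose and 4 fell, and 11 and 5 adjusted over the list alone (median 0.17, adjusted p = 0.180). The cytokine gene LIF rose by 0.95, CCL2 by 0.58 and NFKBIA, the inhibitor of NF-kB, by 0.43. IL1A and CXCL8 fell by 0.72 and 0.29. CXCL1 and CCL20, named after their values were seen, fell by 0.76 and 0.57. IL6 stood at -0.16 (adjusted p = 0.0646), and was called without replicate 3 at 0 h (-0.20) or replicate 1 at 3 h (-0.19). Of 14 complement and inflammasome genes 5 fell, 4 of them also adjusted over the list alone (median -0.13, adjusted p = 0.238). Besides CASP1, IL18 fell by 0.59, CFB by 0.39, PYCARD by 0.27 and SERPING1, named after its value was seen, by 0.20. Of 22 interferon-stimulated genes 3 rose and 8 fell, the same adjusted over the list alone (median -0.07, adjusted p = 0.522), from OAS3, which rose by 0.79, to HERC5, which fell by 0.52. OAS2 and MX1, named after their values were seen, rose by 0.32 and 0.24.

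Among metabolic lists, 9 of 17 glycolysis genes rose and 2 fell, the same adjusted over the list alone (median 0.14, camera adjusted p = 0.0861), with the pyruvate kinase gene PKM rising by 0.85 and the hexokinase gene HK1 by 0.62. LDHB and ALDOC, named after their values were seen, fell by 0.22 and 0.21. Of 20 hypoxia genes 11 fell and 5 rose, the same adjusted over the list alone (median -0.17, adjusted p = 0.443). PDK1, which restrains pyruvate dehydrogenase, fell by 0.66 and ANKRD37 by 0.67, while PFKFB3 rose by 0.36 and VEGFA by 0.21. LOX, NDRG1 and the glucose transporter gene SLC2A1, named after their values were seen, rose by 0.40, 0.27 and 0.22. Without shared or cross-hybridizing probe sets VEGFA turned to -0.04. Of 16 cholesterol synthesis genes 4 rose and 8 fell, the same adjusted over the list alone (median -0.12, adjusted p = 0.788), with SREBF2 rising by 0.58 and DHCR7 by 0.42. LSS rose by 0.49 and FDPS, named after its value was seen, by 0.15. The squalene epoxidase gene SQLE fell by 0.36, and was not called without shared or cross-hybridizing probe sets (-0.03).

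Lists of cell identity markers did not pass camera after adjustment in the main fit. Of 15 tested retinal pigment epithelium markers 6 rose and 3 fell, the same adjusted over the list alone (median 0.18, camera adjusted p = 0.195). The keratin genes KRT8 and KRT18 rose by 0.40 and 0.34 and the transporter gene SLC6A15 fell by 0.34. SERPINF1, which encodes pigment epithelium-derived factor, and RDH11, both named after their values were seen, fell by 0.40 and 0.25. RPE65 (3.48 in both groups) and RLBP1 (4.20 in both groups) were under the floor of 4.64. Of 16 mesenchymal and matrix genes 3 rose and 5 fell, the same adjusted over the list alone. ZEB1 fell by 0.62, S100A4 by 0.59 and POSTN by 0.50. Named after their values were seen, TGFB1, TGFBI and MMP2 rose by 0.40, 0.38 and 0.25 and ZEB2 fell by 0.33. The median of 0.01 lay above 0 while the mean of -0.09 and camera (adjusted p = 0.806) pointed down. TAGLN, 0.42 lower, turned to 0.19 without shared or cross-hybridizing probe sets, and ZEB1 and POSTN stood at -0.04 and -0.27 averaged over their probe sets. Of 17 TGF-beta, BMP and YAP targets 8 rose and 5 fell, and 9 and 6 adjusted over the list alone (median 0.13, adjusted p = 0.232). ID1, a BMP target, fell from 9.74 ± 0.03 to 8.66 ± 0.13 (n = 3, adjusted p = 2.84e-05), and the YAP target gene AMOTL2 rose by 0.84, or 0.45 averaged over its probe sets. SKIL, ID3, ID4 and ANKRD1, named after their values were seen, fell by 0.45, 0.42, 0.28 and 0.27. Of 7 blood and endothelial markers 0 passed in limma, also adjusted over the list alone, and CD3E (0.23) and VWF (-0.18) had unadjusted p values of 0.0378 and 0.0468. CD3E was called without replicate 3 at 3 h (0.30). Camera placed that list upward (adjusted p = 0.806), with a mean of 0.00 and a median of -0.04. Of 8 photoreceptor and neuronal markers 2 fell, PDE6B by 0.36 and SYT1 by 0.22, the same adjusted over the list alone (median -0.12, adjusted p = 0.608). PDE6B turned to 0.11 without shared or cross-hybridizing probe sets and SYT1 to 0.06 averaged over its probe sets.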

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

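The tests with the gene density trend removed, the test of fewer dividing cells, and the bootstrap and binomial intervals, with the bounds they were held to, were chosen after the results were seen. Some control probe sets, which were left out of the tests of genes, were above the 0 h level on all 3 h arrays: those for the 3′ and 5′ parts of 18S ribosomal RNA by 0.65 and 0.51, and those for the 5′ part and the middle of actin by 0.97 and 0.65 (log2). The control probe set for the 3′ part of actin changed by 0.10. Among the tested genes, the actin gene ACTB was called at 0.60 by its brightest probe set. Its 2 other probe sets above the floor changed by 0.06 and 0.15, so the size of that call depends on the probe set. Among 2341 probe sets without a single gene symbol, 591 were higher and 530 lower at 3 h (limma), and the largest increase was 2.23.

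Of the 10 splits of the 6 arrays, only the real one called genes in limma (6273, highest other 0). The others had 63 to 278 genes at an unadjusted p under 0.05 against 7041. Only the real split had genes changed at least 2-fold (122, highest other 0). The other splits mix arrays of both groups, and 10 splits are too few for a share under 0.05. A trend with signal level stays open, since arrays brought to nearly one distribution leave little of it to see (Spearman rho -0.0642 across genes, 95% interval -0.0807 to -0.0464). Base composition may contribute, because the change rose with the number of neighbouring genes, a proxy for it (rho 0.280 across genes, interval 0.263 to 0.296). Coverage towards the 5′ end may contribute too. Dimmer probe sets changed by a median of 0.0582 more than the brightest of their gene. Where they lie in the transcript was not examined, so that value is no direct measure of such coverage. The spike controls and the 5′ signal differ between all arrays of the groups, so a batch, the treatment and the construct named in the descriptions cannot be told apart. Handling and time after transfection may differ with them, since no group kept without the enzyme for the same time is listed.

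For the rise of immediate early genes, the trend with gene density as the whole cause is argued against, since with that trend removed the median went from 0.152 to 0.136 (interval 0.0188 to 0.285) and the list still passed camera (adjusted p = 0.0170, against 0.000982 to 0.491 over all settings of the median log2 change of Immediate early genes, the highest with an estimated correlation). The trend took a median of 0.00643 from its members (interval -0.107 to 0.0541), which says nothing of composition beyond that proxy. Of 34 other probe sets of the called members 28, or 82.4%, had the sign of the brightest (exact binomial interval 65.5% to 93.2%), about the 82.0% found over all called genes, so 5′ coverage stays open. Exposure to peroxide, the difference the design names, is a further open explanation.

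For the fall of centromere and kinetochore genes, the trend with gene density as the whole cause is argued against, since the median stayed at -0.270 with that trend removed (before, -0.341; interval -0.425 to -0.158) and the trend took a median of -0.0541 from its members (interval -0.0983 to 0.0213), which says nothing of composition beyond that proxy. A loss of dividing cells that lowers DNA replication genes as much as this list is argued against. Those genes had a median of 0.0854 (interval -0.0472 to 0.198, which spans 0) and did not pass camera (adjusted p = 0.238). Mitosis genes had -0.167 (interval -0.426 to -0.0553), so a smaller share of cells near mitosis was not excluded, and fewer dividing cells as such stay open. Coverage towards the 5′ end cannot be told apart from a change of these genes, because 76.9% of only 13 other probe sets had the same sign (exact binomial interval 46.2% to 94.96%). The treatment and the alpha satellite construct named in the descriptions remain open and were not tested against each other. For the count of lists past camera, 2 of the 10 splits gave as many: the real one and 1 that mixed arrays of both groups, with 2 lists each. That count, which includes immediate early genes and this list, therefore does not set the real split apart from chance. The 10 splits are also too few for a share under 0.05.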

How the results depend on the processing

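The removal of the gene density trend was chosen after the data were seen; the other settings were fixed before. The counts of genes higher, lower and changed at least 2-fold either way, and of lists, stayed within 1.5 times their values in the settings run for them, except where named here. The threshold of 0.01 was run for genes higher and lower only, and immediate early genes (adjusted p = 0.0182) would not pass it. With each array left out in turn 2081 to 2525 genes were higher, 3114 to 3627 lower, 117 to 133 changed at least 2-fold and 2 to 3 lists passed. Testing every probe set gave 6976 higher, 7096 lower and 439 changed at least 2-fold. It counts several probe sets per gene, 27235 in place of 12221 genes, and the cause of the rest of the difference was not tested. Genes at least 2-fold lower alone went from 31 to 19 with the stricter filter on dim genes, which tests fewer genes, and to 15 with the gene density trend removed. With the mean of all probe sets the number of genes changed at least 2-fold was 65, 12 of them lower. A 1.5-fold minimum in place of 2-fold counted 1104 genes, more by its construction. The lists past the test numbered 4 with quantile normalization and with the gene density trend removed, 7 with no filter on dim genes, with the mean of all probe sets and without x_at and s_at probe sets, 8 with a trend and robust prior, 24 with fry, which asks another question, and 0 with an estimated correlation. That setting left the median log2 change of Immediate early genes at 0.15 and the median log2 change of Centromere and kinetochore genes at -0.34, with adjusted p = 0.491 for both. Over all settings these adjusted p values ran from 0.000982 and from 6.88e-05 up to that, and with each array left out in turn the medians ran from 0.11 to 0.18 and from -0.36 to -0.30. Called genes turned sign with the mean of all probe sets (DUSP1 0.11, SYT1 0.0619, TAGLN 0.00593) or without x_at and s_at probe sets (PDE6B 0.11, PDIA3 -0.10, TAGLN 0.19, TNFRSF10B -0.0500, VEGFA -0.044), and TXNIP, not called before, was called at 0.22. These settings use other probe sets of the gene, and beyond that the cause was not tested. Of 2604 comparisons of 166 named genes 2523 stayed on their side of the threshold, 55 lost and 17 gained a call. Of 501 for the other 28 lists 449 stayed and 52 gained one, 22 of these with fry, which asks another question. The replicate numbers did not pair the arrays (correlations of same-numbered deviations -0.04, -0.02 and -0.19), and the replicate block called 2336 genes higher, 3502 lower, 122 at least 2-fold and 2 lists. Alternatives for linear values were not run because the values are log2. No detection calls were used here, so signal over background limits the dim genes to the floor of 4.64.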

Other observations

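The trend on gene density was examined and removed after the results were seen. Chromatin genes were divided. Of 18 heterochromatin genes 7 rose and 6 fell, the same adjusted over the list alone (median 0.03, camera adjusted p = 0.569): the maintenance DNA methyltransferase gene DNMT1 rose by 0.70 and the corepressor gene TRIM28 by 0.41, and the remodeller gene HELLS fell by 0.85 and SUV39H2 by 0.37. Its relative SUV39H1 rose by 0.36, but stood at 0.18 averaged over its probe sets and at 0.03 without x_at and s_at probe sets. Of 14 histone genes 4 rose and 4 fell, the same adjusted over the list alone (median -0.12, adjusted p = 0.788), with the damage-associated variant gene H2AX rising by 0.79 and the replication-dependent H2AC8 falling by 0.58. H4C8 and H2BC5 fell by 0.42 and 0.28, and H2BC5 was not called averaged over its probe sets (-0.09). Named after their values were seen, H2BC4 fell by 0.23, and H1-4, H2BC21 and H3-3B rose by 0.32, 0.19 and 0.18. Of 317 zinc finger genes 139 fell and 47 rose, and 143 and 50 adjusted over the list alone (median -0.17, adjusted p = 0.0936). ZNF555 fell by 0.74 and ZNF703 rose by 0.89, or 0.50 averaged over its probe sets. With the gene density trend removed, the list passed camera with a median of -0.19. With the trend kept, it had an adjusted p = 0.525 with an estimated correlation.

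Of 24 nuclear genes of the mitochondrial respiratory chain 12 fell and 2 rose, and 14 and 2 adjusted over the list alone (median -0.17, camera adjusted p = 0.132). NDUFA2 fell by 0.46 and NDUFB3 by 0.44, and CYC1 and SDHA, named after their values were seen, rose by 0.16 and 0.28. Of the genes encoded in mitochondrial DNA, named after their values were seen, ND1 rose by 0.93 and ND4 by 0.59, and COX3 stood at -0.20 (adjusted p = 0.0869). Of 70 ribosomal protein genes 15 fell, 1 rose and 54 did not pass, and 14 and 1 adjusted over the list alone (median -0.08, adjusted p = 0.180). RPL7 fell by 0.63, and RPL8, named after its value was seen, rose by 0.22. Of 18 autophagy and lysosome genes 6 rose and 6 fell, the same adjusted over the list alone: the lysosomal genes CTSD and LAMP1 rose by 0.62 and 0.44, and TFEB, their transcriptional regulator, fell by 0.46. Camera placed that list upward (adjusted p = 0.784) with a median of -0.04 and a mean of -0.00. Of 16 apoptosis regulators 3 rose and 1 fell, the same adjusted over the list alone (median 0.02, adjusted p = 0.522), BCL2L1, BAX and BBC3 rising by 0.36, 0.31 and 0.29 and BIRC2 falling by 0.26. BAX was not called with the gene density trend removed (0.23).

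Genes with few neighbours were lower more often. In the fifth of genes with 0 to 6 other protein-coding genes within 500 kb, 1419 of 3046 fell and 394 rose (median -0.17), and in the fifth with 28 to 75 neighbours 343 of 2361 fell and 652 rose (median 0.06). With that trend removed, 2815 genes were higher and 3233 lower; 2206 were higher and 2885 lower in both fits, and 0 of the limma calls in both fits were opposite.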
